A study of Mus musculus with 15 samples.

How the data were processed

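RNA was measured by bulk RNA sequencing in heart tissue of male C57BL/6J mice in 3 groups of 5 libraries each. The control group holds replicates 1, 4, 5, 7 and 10. The other groups had received a high fat diet together with L-NAME, an inhibitor of nitric oxide synthases, at 0.5 g/L for 5 weeks (replicates 21, 23, 28, 29 and 30) or for 7 weeks (replicates 31, 32, 34, 39 and 40). This diet and drug combination is used to bring about heart failure with preserved ejection fraction in mice. The labels do not say when the control hearts were taken or what the control mice were fed. Hearts were frozen in liquid nitrogen, RNA was taken up in Trizol and libraries were made with a NEBNext Ultra kit, per the labels' protocols. The labels number the libraries but do not say in so many words that each came from its own mouse, so p-values measure the spread between these libraries.

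HISAT2 2.0.0, StringTie 1.2.4 and limma are named in the submitters' processing notes, which also name the genome builds mm10 and hg38 without saying which step used which. The column of values is called FPKM, per the file headers, but the deposited values are whole numbers that sum to between 15138097 and 43795879 per library. In true FPKM, the values times exonic length, scaled back to a share of fragments, add up to at most 1 per library; these added up to between 90.0 and 255, so they cannot be FPKM. They were handled as estimated counts per gene as deposited by the authors, and needed no rounding because they were already whole. How the whole numbers were made is not given in the sources used here. Low values fell on multiples of 4 more often than on their neighbours, with 13379 gene-library values at 4 against 5991 at 3 and 8466 at 5. Each file held 2 columns, a gene identifier and 1 value, for 55421 identifiers. Of these, 55154 were matched to a symbol by identifier in GENCODE release M21 for GRCm38 (mm10), and the remaining 267 carried at most 0.00229% of the counts of a library. The file of 5-week replicate 28 held 10114 further empty lines, which were dropped. Coordinates are those of GRCm38. No strand setting is given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart. This touches 7 of the 91 named genes that were checked, whose exons overlap those of a gene on the opposite strand over at least 10% of their length (Bnip3, Dbp, Nos3, Nppa, Pln, Scgb1c1 and Timp3). A few further genes named in the text were not checked. Acot2, Chil3, Gsta3, Ms4a4a, Retnla, Retnlg and Serpina3n belong to families of similar genes and may share reads with relatives, so their values are less certain.

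Genes with low counts were removed with edgeR's filterByExpr by group, which left 16873 genes and removed 38548. Library sizes were scaled with TMM. All 15 libraries were fitted together with 1 coefficient per group and 12 residual degrees of freedom, and each contrast was tested with edgeR 4.0.16's quasi-likelihood F test (robust) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The contrasts were 5 weeks against control, 7 weeks against control and 7 weeks against 5 weeks. The common biological coefficient of variation was 0.448. Standard errors of log2 fold changes were derived from the F statistic. No technical batch is given in the labels.

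Gene lists, cell type markers, the rule for naming genes, the main tests and most alternatives were fixed before the data were examined. The lists were 24 pathways and 18 sets of cell type or tissue markers. Each list with at least 3 tested members was compared with all other tested genes by camera (limma 3.58.1, voom weights, preset inter-gene correlation 0.01), adjusted over the 42 lists of a contrast. Beside it stand camera with an estimated correlation and fry. The fry test asks whether the genes of a list move on balance one way, without comparing them with other genes. The pathway lists covered fatty acid oxidation and PPAR targets, cardiac stress genes, the adult sarcomere, calcium handling, extracellular matrix, unfolded protein response, heat shock, circadian clock, immediate early genes, cholesterol synthesis, lipogenesis, glucose use, nuclear oxidative phosphorylation, genes encoded by mitochondrial DNA, nitric oxide and cGMP, renin, angiotensin and natriuretic signalling, antioxidant enzymes, hypoxia and angiogenesis, innate inflammation, interferon response, antigen presentation, cell cycle, autophagy and atrophy, and iron and haem. The marker lists covered cardiomyocytes, atrial muscle, endothelium, fibroblasts, mural and smooth muscle cells, macrophages, neutrophils, B cells, T and NK cells, erythroid cells, white and brown adipocytes, skeletal muscle, Schwann and neural cells, mesothelium, lung and airway, thymus and liver. Some genes stand in more than 1 list.

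The genes named per contrast were (a) the 6 rising and 6 falling called genes with the largest fold changes among those with a mean of at least 2 CPM (counts scaled to a common library size) and an established symbol, (b) up to 2 rising and 2 falling called members of each list by smallest p, or the member with the smallest p where none was called, and (c) a fixed panel of 24 genes. Where fewer than 6 genes passed in (a), those with the smallest p up to 6 were taken. Not every gene under this rule is named.

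The overlap of the contrasts against the shared controls was set against 100 simulated data sets in which neither group differed from the controls, against the overlap of independent lists, and against all 10 splits of the controls into 2 and 3 libraries, each with both assignments (20 fits). Group differences in library totals and in mean log2 CPM of marker genes were tested by exact two-sided permutation over 252 regroupings. The atrial score was the mean over Myl4, Myl7, Sln and Mybphl. The white adipocyte score was the mean over Adipoq, Plin1, Cidec, Cfd and Car3, where tested, and left out Fabp4 and the rest of that list.

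The alternatives were RLE size factors, upper-quartile factors, no low-count filter, a filter of at least 5 CPM in 5 libraries, mitochondrial-genome and haemoglobin genes left out, only the 2 groups compared, DESeq2 1.42.0, limma-voom with and without quality weights, surrogate variables (sva 3.50.0), added fold thresholds, an FDR of 0.1 for the overlap, and each of the 15 libraries left out in turn. Chosen after seeing the data were near-zero values set to missing, only genes with 3 or more exons, the libraries with adipose transcripts left out together, 7-week replicates 31 and 32 left out together, an atrial score as covariate, and further settings of the overlap.

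The fit was tested on simulated counts for the real genes and library sizes with 200 changed genes. For 5 weeks against control, over 16285 genes, 7.58% of genes changed by 0.5 on the log2 scale were recovered, 61.2% of those changed by 1 and 86.6% of those changed by 2, with 2 false calls among 106. For 7 weeks against control, over 16317 genes, these shares were 15.2%, 55.2% and 80.6%, with 4 false calls among 105. No recovered gene had the wrong sign. A list shifted by the simulation was recovered in both contrasts, and no other list was called. The simulated genes were drawn independently of each other. The simulation therefore does not show how often lists of correlated genes are called without a change.

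Libraries were compared before averaging. The correlation of log2 CPM between any pair lay between 0.899 and 0.927, and at most 43 values above 100 were identical in a pair, and no pair was taken for a single library. Of 9238 genes with a mean of at least 10 CPM, 266 (2.88%) had a library below 10% of its own group's median. Among protein-coding genes these near-zero values touched 67.6% of genes with 1 exon, 47.2% with 2 exons, 4.15% with 3 to 5 and 0.194% with 6 or more. No called gene with a mean of at least 10 CPM had such a library, and 21 of the 170 genes called at 5 weeks and 50 of the 297 called at 7 weeks, Zfp281 among the 50, lay below that mean and were not covered.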

Results

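Messenger RNA was measured in heart tissue of male C57BL/6J mice to find the genes and pathways that change in HFpEF, a form of heart failure in which the share of blood ejected per beat stays normal, as modelled in mice. There were 5 control libraries, 5 taken after 5 weeks of high fat diet and L-NAME, and 5 taken after 7 weeks. The total count per library ran from 39419070 to 43795879 in controls and from 36040590 to 41032190 at 5 weeks. At 7 weeks it ran from 36063309 to 39072276 in 4 libraries and was 15138097 in 7-week 32, which also had the fewest genes above 0 (18014, against 19818 to 20729 in the others). Totals were lower than in controls at 5 weeks (exact two-sided permutation p = 0.0397) and at 7 weeks (p = 0.00794, the smallest the design allows), and the exact test between 5 and 7 weeks gave p = 0.214. Myh6, the main myosin heavy chain of the adult mouse heart, took 3.60% ± 0.263 of the counts in controls, 2.64% ± 0.309 at 5 weeks and 3.01% ± 0.119 at 7 weeks (SD, n = 5 each). Transcripts of mitochondrial DNA made up 0.00236% ± 0.00314 of the counts in controls and 0.00510% ± 0.00205 at 5 weeks (SD, n = 5 each). In 7-week 31 they made up 0.479% (95% Wilson interval 0.477% to 0.482%, counting error only), with 152148 counts of the ribosomal RNA mt-Rnr2. The mitochondrial mRNA mt-Co1 had 0 or 1 count in 4 of the 5 controls and at least 385 counts in the other 11 libraries. The cause of this split was not tested. If most controls were processed differently, that could not be told apart from the treatment in the contrasts against control. The mitochondrial shares and counts are those of the deposited values. How these were made is not given, so they were not read as amounts in the tissue. Adipoq, a hormone made by fat cells, stood at 4.73 CPM (counts scaled to a common library size) in control 5, 9.87 CPM in 5-week 28 and 13.0 CPM in 7-week 34, and at no more than 0.725 CPM in the other 12 libraries. The first 3 principal components of log2 CPM held 9.56%, 8.62% and 7.89% of the variance. On the first of them 7-week 32, the library with the fewest counts, stood at 105 and the other 14 between −38.2 and 30.1.

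The first comparison asked which genes had changed after 5 weeks of the model. Of 36 genes of fatty acid oxidation 5 were higher than in controls, and 6 of 22 sarcomere genes and 3 of 24 cholesterol genes were lower. The 3 lists passed the camera test, with adjusted p of 0.131, 0.0507 and 0.0146 with an estimated correlation. Fabp3, which carries fatty acids inside heart muscle cells (ENSMUSG00000028773, GRCm38 chromosome 4, 130308595 to 130315463), rose 1.62-fold from 3818 ± 480 CPM in controls to 6178 ± 324 CPM (SD, n = 5 each). Its log2 fold change was 0.69 (SE 0.08), with an adjusted p of 0.00163 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cd36, which takes up fatty acids at the cell surface (chromosome 5, 17781690 to 17888801), rose from 2080 ± 188 to 3114 ± 307 CPM (log2 fold change 0.58, SE 0.10; edgeR adjusted p = 0.0102). Tnnt2, cardiac troponin T (chromosome 1, 135836354 to 135852260), fell from 9249 ± 456 to 7343 ± 260 CPM (log2 fold change −0.33, SE 0.04; edgeR adjusted p = 0.0036).

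Of 36 genes of fatty acid oxidation and PPAR targets tested at 5 weeks, 5 rose, 0 fell and 31 did not pass, against 22 risen and 0 fallen when adjusted over the list alone. The median log2 fold change of the list was 0.29 (camera adjusted p = 5.82e-18; adjusted p = 0.131 with an estimated correlation; fry adjusted p = 0.00426). Pdk4, which turns off glucose oxidation, had a log2 fold change of 2.17 (SE 0.76), Angptl4, an inhibitor of lipoprotein lipase, 1.80 (SE 0.46) and Ucp3, a mitochondrial uncoupling protein, 0.97 (SE 0.32), and none of the 3 passed. Pparg, a regulator of fat storage genes (log2 fold change 0.78, SE 0.15), and Gpam, which starts triglyceride synthesis (1.2, SE 0.23), rose among the genes of lipogenesis, a list that was not called. Fabp4, a fatty acid carrier of endothelium and fat cells, rose (log2 fold change 0.83, SE 0.11). It was the 1 riser among 12 endothelial markers (2 risen adjusted over the list alone; median log2 fold change 0.15; camera adjusted p = 0.00773; adjusted p = 0.495 with an estimated correlation). Fabp4 was also the 1 riser among 9 white adipocyte markers, of which 8 were positive (median log2 fold change 0.63; camera adjusted p = 0.328). The white adipocyte score, which covers part of this list and leaves out Fabp4, differed by 0.22 from controls (exact two-sided permutation p = 0.794).

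Of 22 genes of the adult sarcomere tested at 5 weeks, 0 rose, 6 fell and 16 did not pass, with 10 fallen when adjusted over the list alone. Beside Tnnt2 these included Myh6 (log2 fold change −0.48, SE 0.08; edgeR adjusted p = 0.0127) and Mybpc3, the cardiac myosin binding protein C (−0.51, SE 0.07). The median of the list was −0.26 (camera adjusted p = 1.03e-10; adjusted p = 0.0507 with an estimated correlation; fry adjusted p = 0.000625). The 10 cardiomyocyte markers gave 1 riser, Fabp3, and 3 that fell, with 2 risen and 3 fallen when adjusted over the list alone (median −0.16; camera adjusted p = 0.0206; adjusted p = 0.495 with an estimated correlation). Of 32 genes of calcium handling, 1 fell, the potassium channel Kcnd2 (log2 fold change −0.62, SE 0.12), and 3 fell when adjusted over the list alone (median −0.13; camera adjusted p = 0.0172; adjusted p = 0.495 with an estimated correlation). In the list of cardiac stress genes, which was not called, the magnesium transporter Slc41a3 fell (log2 fold change −1.18, SE 0.18). The natriuretic peptide genes Nppa and Nppb did not pass (−0.33, SE 0.58, and −0.24, SE 0.27; Nppa 0.59 without control 5), nor did Myh7 (−0.32, SE 0.15), Acta1 (0.33, SE 0.19; 0.13 without 5-week 28) or Ankrd1 (−0.03, SE 0.18).

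Of 24 genes of cholesterol synthesis tested at 5 weeks, 3 fell, 0 rose and 21 did not pass, with 11 fallen when adjusted over the list alone. Sqle, squalene epoxidase, had a log2 fold change of −1.49 (SE 0.28). The median of the list was −0.33 (camera adjusted p = 8.47e-09; adjusted p = 0.0146 with an estimated correlation; fry adjusted p = 0.000156). Of 34 genes of glucose use, 5 fell and 0 rose, against 2 risen and 8 fallen when adjusted over the list alone (median −0.11; camera adjusted p = 0.00773; adjusted p = 0.495 with an estimated correlation). Among them were Slc2a4, the insulin-regulated glucose transporter (log2 fold change −0.29, SE 0.05), and Eno3, muscle enolase (−0.48, SE 0.08). None of 42 nuclear genes of oxidative phosphorylation was called, and 3 fell when adjusted over the list alone (median −0.09; camera adjusted p = 0.00077; adjusted p = 0.495 with an estimated correlation). Uqcrc1, a core subunit of complex III, stood at −0.24 (SE 0.06).

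Clock genes moved both ways at 5 weeks. Of 22 tested, 3 rose and 2 fell, against 5 risen and 3 fallen when adjusted over the list alone. Per2 and Cry1, which repress the clock, rose (log2 fold change 1.40, SE 0.21, and 0.67, SE 0.11). Arntl, which drives the clock, and its repressor Nr1d1 fell (−1.54, SE 0.31, and −1.03, SE 0.17). The list's median was 0.15 (camera adjusted p = 0.0316; adjusted p = 0.495 with an estimated correlation). Dbp, a target of the clock, stood at −0.01 (SE 0.30) and turned sign without single libraries. The hour at which the hearts were taken is not in the labels. Fkbp5, a gene that glucocorticoids switch on, rose (log2 fold change 1.47, SE 0.29).

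Markers of immune and other cells at 5 weeks were mostly below the threshold gene by gene. The 9 neutrophil markers gave 0 calls, with 3 risen when adjusted over the list alone (median 1.49; camera adjusted p = 0.0039; adjusted p = 0.495 with an estimated correlation). With a filter of at least 5 CPM in 5 libraries the camera adjusted p of the neutrophil list was 0.0666. Retnlg, a secreted neutrophil protein, stood at 2.27 (SE 0.57), and none of 37 genes of innate inflammation was called, over all genes or adjusted over the list alone (median 0.23; camera adjusted p = 0.0202; adjusted p = 0.625 with an estimated correlation). Il1b, an inflammatory cytokine, stood at 0.98 (SE 0.26). Antigen presentation had 0 calls among 23 on either scale, with Tap1 at −0.45 (SE 0.15; median −0.21; camera adjusted p = 0.00773; adjusted p = 0.793 with an estimated correlation). Schwann and neural markers had 0 calls among 8 on either scale (median −0.41; camera adjusted p = 0.0316; adjusted p = 0.495 with an estimated correlation). In the uncalled list of macrophage markers Cx3cr1, a chemokine receptor, stood at −1.05 (SE 0.24). Gsta3, a glutathione transferase, rose as 1 of 33 antioxidant genes (log2 fold change 1.06, SE 0.14; 4 risen and 1 fallen adjusted over the list alone; median 0.11; camera adjusted p = 0.0331; adjusted p = 0.495 with an estimated correlation). Dnaja1, a chaperone partner, rose as 1 of 22 heat shock genes (log2 fold change 1.04, SE 0.14; 5 risen adjusted over the list alone; median 0.10; camera adjusted p = 0.043; adjusted p = 0.495 with an estimated correlation).

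Among genes named for the size of their change at 5 weeks, Chrna2, a nicotinic receptor subunit, rose (log2 fold change 2.63, SE 0.41), as did Fam107a (1.64, SE 0.36), Serpina3n, a protease inhibitor (1.48, SE 0.31), and Ms4a4a (1.46, SE 0.29). Spon2, a secreted matrix protein, fell (−2.15, SE 0.37), as did the early growth response factor Egr1 (−1.85, SE 0.32), Scgb1c1 (−1.73, SE 0.21), Lingo3 (−1.44, SE 0.23) and the phosphodiesterase Pde1c (−0.61, SE 0.08). Bnip3, a receptor for removal of mitochondria, and Mme, the peptidase neprilysin, rose (0.65, SE 0.13, and 0.81, SE 0.16). Of a fixed panel of 24 genes 5 were called, Cd36, Myh6, Arntl and Fkbp5 among them. The 19 that were not had an adjusted p between 0.081 and 0.998. They included the collagens Col1a1 (log2 fold change −0.52, SE 0.18) and Col3a1 (−0.67, SE 0.24), the matrix gene Postn (0.28, SE 0.24), the nitric oxide synthases Nos2 (−0.31, SE 0.11) and Nos3 (−0.08, SE 0.08) and the stress genes Xbp1 (−0.04, SE 0.12) and Hspa5 (−0.14, SE 0.13). The calcium pump Atp2a2 (−0.13, SE 0.12), its brake Pln (0.64, SE 0.21) and Cyp1a1 (1.65, SE 0.45) did not pass either, nor did the matrix protease inhibitor Timp3 (0.50, SE 0.11; edgeR adjusted p = 0.051).

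In edgeR's test 78 genes were higher and 92 lower at 5 weeks among 16873 tested, with 2144 genes at an unadjusted p below 0.05. Of the called genes, 20 rose and 18 fell at least 2-fold. In 164 of the 170 called genes, and in 30 of the 31 named ones (all but Kcnd2), every 5-week library lay on 1 side of every control. The calls came from these same libraries, so this separation is no further support for them. Over all tested genes 4.86% showed it, against 0.794% by chance. Of 42 lists 15 were called, and among these the adjusted p with an estimated correlation ran from 0.0146 to 0.793 and passed only for cholesterol synthesis. The fry test passed for 3 lists, fatty acid oxidation, sarcomere and cholesterol synthesis. The other 27 lists had camera adjusted p between 0.0801 and 0.884, and 7 of their members rose and 3 fell, counting a gene once per list. In 9 lists, none of them called, the median, mean and test differed in sign (cardiac stress, unfolded protein response, immediate early, mitochondrial DNA, nitric oxide, cell cycle, fibroblast, erythroid and brown adipocyte). The count of 170 fell to 82 without control 4, to 104 without control 5, to 100 without control 7, to 100 without 5-week 28 and to 104 without 5-week 30, and 123 genes were higher without 7-week 31. With control 5, 5-week 28 and 7-week 34 left out together it was 16 higher and 19 lower, and DESeq2 called 321 higher and 324 lower.

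At 5 weeks 12 of the named calls lay near the threshold and were lost without single libraries, at log2 fold changes of 79.9% to 106% of those over all libraries. Fam107a and Serpina3n were lost without 7-week libraries too, which are outside the contrast. Arntl lost its call without control 4 (edgeR adjusted p = 0.0641), control 7 (0.0721), 5-week 23 (0.0658), 5-week 28 (0.0716) or 5-week 29 (0.0611), and Sqle without control 4 (0.0641), 5-week 23 (0.0566), 5-week 28 (0.0621) or 5-week 29 (0.052). Pparg lost it without control 4 (0.0619), control 5 (0.0566) or 5-week 30 (0.0534), Mme without control 4 (0.0518), control 5 (0.0606) or 5-week 28 (0.0515), and Slc2a4 without control 7 (0.0502), control 10 (0.0515) or 5-week 28 (0.0515). Fkbp5, Ms4a4a, Gpam and Bnip3 each lost it without any 1 of 7 libraries (adjusted p up to 0.0794, 0.074, 0.0657 and 0.0738), Kcnd2 without any 1 of 8 (up to 0.081), Serpina3n without any 1 of 11 (up to 0.106) and Fam107a without any 1 of 12 (up to 0.12). Among the lists, calcium handling was lost without control 10 (camera adjusted p = 0.0725) or 5-week 30 (0.053), endothelium without 5-week 30 (0.053) and the clock without control 4 (0.133), control 5 (0.147), 5-week 21 (0.0993) or 5-week 30 (0.053). Innate inflammation was lost without control 7 (0.0781), control 10 (0.129) or 5-week 29 (0.138), and antigen presentation without control 1 (0.0663), control 5 (0.0541), 5-week 21 (0.217) or 5-week 23 (0.0558). Antioxidant genes lost the call without control 5 (0.0541), control 10 (0.0725), 5-week 21 (0.128) or 5-week 29 (0.095). Heat shock genes and Schwann markers each lost it without any 1 of 5 libraries (up to 0.158 and 0.13).

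**Figure D1:**
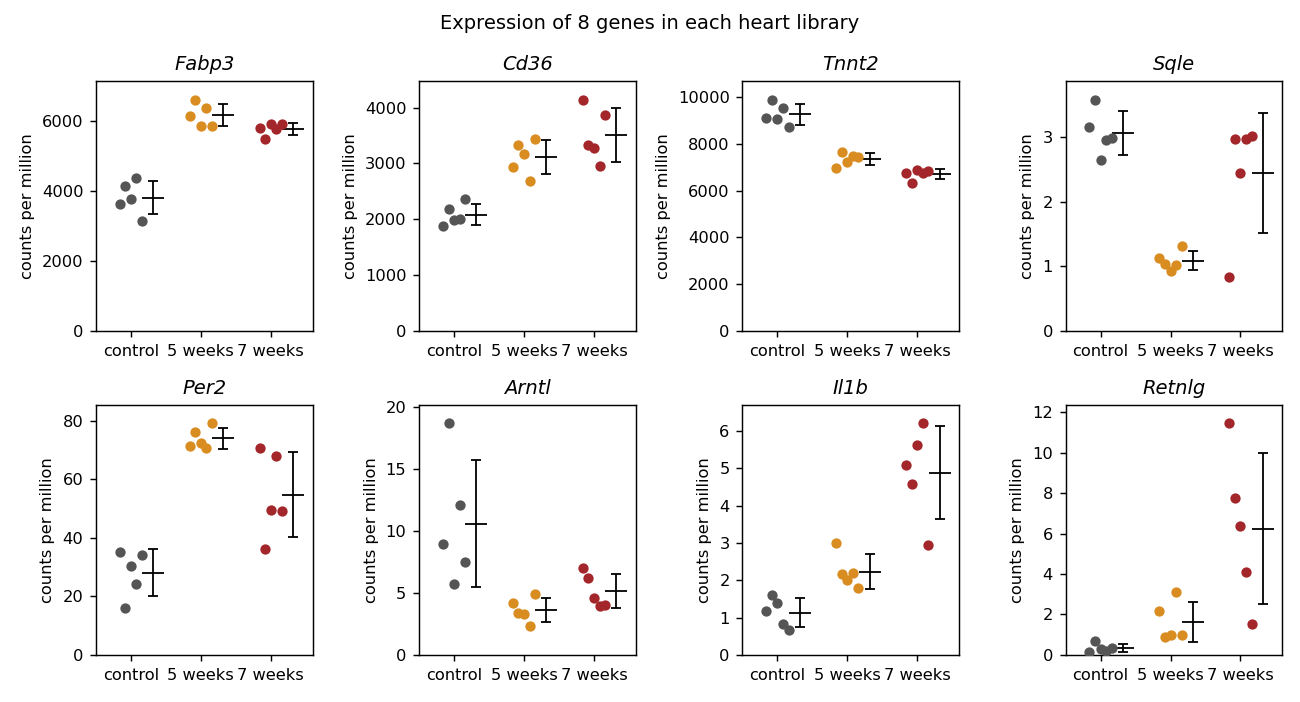
Expression in CPM of 8 genes in control, 5-week and 7-week hearts, with 1 point per library and a bar for the mean ± SD (n = 5). The mean of Cd36 was 2080 CPM in controls, 3114 CPM at 5 weeks and 3514 CPM at 7 weeks, and that of Tnnt2 fell from 9249 to 7343 and 6711 CPM.

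The second comparison asked which genes differed from control after 7 weeks of the model. Of 36 genes of fatty acid oxidation 10 were higher than in controls, as were 6 of 9 neutrophil markers, and 5 of 22 sarcomere genes and 7 of 42 nuclear genes of oxidative phosphorylation were lower. The 4 lists passed the camera test, each with an adjusted p of 0.0768 with an estimated correlation. Cd36 rose from 2080 ± 188 CPM in controls to 3514 ± 480 CPM (SD, n = 5 each; log2 fold change 0.76, SE 0.10; edgeR adjusted p = 0.00237). Il1b, an inflammatory cytokine (chromosome 2, 129364570 to 129371139), rose 4.31-fold, from 1.13 ± 0.382 to 4.89 ± 1.24 CPM (log2 fold change 2.11, SE 0.27; edgeR adjusted p = 0.00237). Retnlg, a secreted neutrophil protein (chromosome 16, 48872621 to 48874496), rose from 0.336 ± 0.215 to 6.25 ± 3.75 CPM (log2 fold change 4.20, SE 0.61; edgeR adjusted p = 0.00536). Tnnt2 fell from 9249 ± 456 to 6711 ± 219 CPM (log2 fold change −0.46, SE 0.05; edgeR adjusted p = 0.000216). Tnnt1, the troponin T of slow skeletal fibres (chromosome 7, 4504570 to 4516382), fell from 16.4 ± 1.55 to 7.05 ± 1.16 CPM (log2 fold change −1.22, SE 0.14; edgeR adjusted p = 0.00101).

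Of 36 genes of fatty acid oxidation and PPAR targets, 10 rose, 0 fell and 26 did not pass at 7 weeks, with 25 risen when adjusted over the list alone. The median log2 fold change was 0.39 (camera adjusted p = 3.74e-20; adjusted p = 0.0768 with an estimated correlation; fry adjusted p = 0.00154). Risers included Acot2, a mitochondrial thioesterase (1.38, SE 0.17), Fabp3 (0.60, SE 0.07) and Cidea, a lipid droplet protein that also stands among the brown adipocyte markers (0.72, SE 0.14). Ucp3 (1.14, SE 0.32), Angptl4 (1.46, SE 0.46) and Pdk4 (1.67, SE 0.75) did not pass, and without 7-week 31 they stood at 0.96, 1.07 and 0.93. Pparg (1.02, SE 0.15) and Gpam (1.39, SE 0.23) rose, while the lipogenesis list was not called. Fabp4 rose (0.67, SE 0.11) as the 1 riser among 12 endothelial markers (4 risen adjusted over the list alone; median 0.23; camera adjusted p = 5.65e-05; adjusted p = 0.31 with an estimated correlation). Fabp4 was also the 1 riser among 9 white adipocyte markers, all 9 of them positive (median 0.79; camera adjusted p = 0.353). The white adipocyte score, which covers part of this list and leaves out Fabp4, differed by 0.05 from controls (exact two-sided permutation p = 0.952). Catalase, Cat, which breaks down peroxide, rose (0.51, SE 0.11) in an uncalled antioxidant list.

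Of 42 nuclear genes of oxidative phosphorylation, 7 fell, 0 rose and 35 did not pass at 7 weeks, with 26 fallen when adjusted over the list alone. The shifts were small, with a median of −0.19 (camera adjusted p = 1.97e-18; adjusted p = 0.0768 with an estimated correlation; fry adjusted p = 0.000618). Uqcrc1 (log2 fold change −0.35, SE 0.06) and Cyc1 (−0.28, SE 0.05), both of complex III, were among those that fell. Of 22 sarcomere genes 5 fell and 0 rose, with 9 fallen when adjusted over the list alone (median −0.23; camera adjusted p = 6.6e-08; adjusted p = 0.0768 with an estimated correlation; fry adjusted p = 0.00127). They included Tnni3, cardiac troponin I (−0.38, SE 0.06), and Mybpc3 (−0.46, SE 0.07). Myh6 stood at −0.30 (SE 0.08; edgeR adjusted p = 0.0886). Of 10 cardiomyocyte markers 1 rose, Fabp3, and 3 fell, against 1 and 6 when adjusted over the list alone (median −0.29; camera adjusted p = 2.9e-05; adjusted p = 0.0768 with an estimated correlation). Calcium handling genes gave 0 calls among 32, with 2 fallen when adjusted over the list alone (median −0.17; camera adjusted p = 0.0405; adjusted p = 0.501 with an estimated correlation). Kcnd2 stood at −0.51 (SE 0.12), Atp2a2 at −0.18 (SE 0.12) and Pln at −0.23 (SE 0.21). Glucose use was not called as a list, but 5 of its genes fell, among them Eno3 (−0.61, SE 0.08) and the lactate dehydrogenase subunit Ldhb (−0.39, SE 0.07). Cholesterol genes gave 0 calls among 24, with 1 risen and 3 fallen when adjusted over the list alone (median −0.19; camera adjusted p = 0.00166; adjusted p = 0.0987 with an estimated correlation), and Pmvk stood at −0.52 (SE 0.13; edgeR adjusted p = 0.0514).

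Of 9 neutrophil markers tested at 7 weeks, 6 rose and 3 did not pass, and all 9 rose when adjusted over the list alone. The median log2 fold change was 3.27 (camera adjusted p = 8.38e-11; adjusted p = 0.0768 with an estimated correlation; fry adjusted p = 0.00236). S100a8 and S100a9, the calprotectin subunits, had log2 fold changes of 3.27 (SE 0.50) and 2.70 (SE 0.58). Chil3, a secreted protein of myeloid cells, rose (2.72, SE 0.41), and Retnla, a protein of macrophages and fat cells, fell (−1.50, SE 0.29). The mean log2 CPM of the neutrophil transcripts was 2.99 above controls at 7 weeks (exact two-sided permutation p = 0.00794, the smallest possible; 0.0952 adjusted over 12 such tests). Of 37 genes of innate inflammation 5 rose, Il1b, S100a8 and S100a9 among them, with 6 risen when adjusted over the list alone (median 0.20; camera adjusted p = 0.00138; adjusted p = 0.501 with an estimated correlation). Among 9 erythroid markers Slc4a1, the anion exchanger of red cells, rose (1.80, SE 0.38), also when adjusted over the list alone (median 0.37; camera adjusted p = 0.00212; adjusted p = 0.501 with an estimated correlation).

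Of 10 mesothelial markers at 7 weeks, genes of the layer that covers the heart, 1 fell, Msln (−1.11, SE 0.24), and 6 fell when adjusted over the list alone (median −1.10; camera adjusted p = 0.003; adjusted p = 0.501 with an estimated correlation). With an atrial score as a covariate the camera adjusted p of the mesothelial list was 0.0844. Krt7, an epithelial keratin outside the lists, fell (−1.62, SE 0.32). Atrial markers gave 0 calls among 9, with 4 fallen when adjusted over the list alone (median −1.46; camera adjusted p = 0.0809). Myl4, an atrial myosin light chain, stood at −2.49 (SE 0.87) and Nppa, which makes atrial natriuretic peptide, at −1.46 (SE 0.59), and without control 5 at −1.57 (SE 0.78) and −0.54 (SE 0.43). The mean log2 CPM of the 4 transcripts of the atrial score was −1.81 relative to controls (exact two-sided permutation p = 0.127), and −1.17 without control 5. Nppb (0.07, SE 0.27), Myh7 (0.15, SE 0.15), Acta1 (0.06, SE 0.19) and Ankrd1 (0.08, SE 0.18) did not pass, while Slc41a3 fell (−1.04, SE 0.18).

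Of 28 genes of hypoxia and angiogenesis at 7 weeks, 4 rose and 1 fell, against 7 and 1 when adjusted over the list alone (median 0.19; camera adjusted p = 0.0103; adjusted p = 0.222 with an estimated correlation). With a filter of at least 5 CPM in 5 libraries the camera adjusted p was 0.0543. Bnip3 (0.62, SE 0.13) and Ndrg1 (0.38, SE 0.07) rose, and the ephrin ligand Efna1 fell (−0.36, SE 0.08). Among 27 immediate early genes Jun (0.58, SE 0.11) and Klf4 (0.66, SE 0.12) rose, with 3 risen and 1 fallen when adjusted over the list alone (median 0.30; camera adjusted p = 0.0434; adjusted p = 0.501 with an estimated correlation). The cell cycle list passed the camera test on the lower side (median −0.25; camera adjusted p = 0.0391; adjusted p = 0.584 with an estimated correlation), although its 1 called member of 33, Cdkn1a, an inhibitor of the cycle, rose (1.11, SE 0.23), on both scales of adjustment. Of 22 clock genes 1 rose, Per2 (0.97, SE 0.21), with 1 risen and 1 fallen when adjusted over the list alone (median 0.17; camera adjusted p = 0.0406; adjusted p = 0.389 with an estimated correlation). Arntl stood at −1.04 (SE 0.30) and Dbp at −0.05 (SE 0.30). Fkbp5 rose (1.92, SE 0.29).

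By size of change Chrna2 rose (2.67, SE 0.41) and Spon2 (−1.94, SE 0.37), Morn4 (−1.26, SE 0.22) and Pde1c (−0.39, SE 0.08) fell at 7 weeks, and Mme rose (0.68, SE 0.16). Zfp281, a zinc finger gene with 2 exons (chromosome 1, 136624901 to 136630053), had the largest fall among the named genes (−4.11, SE 0.92; edgeR adjusted p = 0.0391), with controls at 2.93 to 27.7 CPM and 7-week libraries at 0.268 to 1.85 CPM. Its mean over all libraries, 6.50 CPM, was below the 10 CPM needed for the check of near-zero libraries, so that check does not cover it. Of the protein-coding genes with 2 exons that were checked, 47.2% had such a library. Of the panel of 24 genes 3 were called, Cd36 and Fkbp5 among them, and the 21 that were not had an adjusted p between 0.0886 and 0.99. Col1a1 (−0.18, SE 0.18), Col3a1 (−0.36, SE 0.24; −0.18 without 7-week 31), Postn (0.04, SE 0.24), Nos2 (0.01, SE 0.11), Nos3 (−0.05, SE 0.08), Xbp1 (0.06, SE 0.12), Hspa5 (0.05, SE 0.13) and Cyp1a1 (1.53, SE 0.44) did not pass. Pi16, a fibroblast gene (0.72, SE 0.17), and Timp3 (0.46, SE 0.11) did not pass either.

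In edgeR's test 172 genes were higher and 125 lower at 7 weeks than in controls among 16873 tested, with 2449 genes at an unadjusted p below 0.05 and a smallest adjusted p of 8.42e-05. Of the called genes, 41 rose and 17 fell at least 2-fold. With upper-quartile scaling 148 were higher and 200 lower, so the higher share was 42.5% in place of 57.9%. In 282 of the 297 called genes, and in 38 of the 40 named ones (all but Mme and Slc4a1), every 7-week library lay on 1 side of every control. Here too the calls came from the same libraries, so the separation adds no support. Of all tested genes 5.48% showed it, against 0.794% by chance. Of 42 lists 15 were called, none of which passed with an estimated correlation, where the adjusted p ran from 0.0768 to 0.584. The fry test passed for 8 lists, which were fatty acid oxidation, sarcomere, cholesterol, oxidative phosphorylation, hypoxia, cardiomyocytes, endothelium and neutrophils. The other 27 lists had camera adjusted p between 0.0672 and 0.97, and 9 of their members rose and 7 fell. In 9 lists, none of them called, the median, mean and test differed in sign (cardiac stress, extracellular matrix, heat shock, mitochondrial DNA, nitric oxide, interferon, iron and haem, B cell and brown adipocyte). The count of 297 fell to 111 without control 4, to 173 without control 5, to 157 without control 7, to 192 without control 10 and to 190 without 7-week 39. It was 55 higher and 24 lower without 7-week 31 and 32, 58 higher and 65 lower with an atrial score as covariate, and 16 higher and 15 lower without control 5, 5-week 28 and 7-week 34, while DESeq2 called 465 higher and 387 lower.

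At 7 weeks 16 of the named calls lay near the threshold and were lost without single libraries, at log2 fold changes of 80.7% to 112% of those over all libraries. That of Mme was lost without 5-week libraries too. Without control 4 the calls of Retnla (edgeR adjusted p = 0.0537), Klf4 (0.0505) and Ndrg1 (0.0528) were lost, without control 7 that of Cidea (0.0505), and without control 5 (0.0502) or control 7 (0.052) that of Krt7. Bnip3 lost its call without control 5 (0.0603), control 7 (0.0653) or control 10 (0.0552), and Per2 without control 4 (0.0528), control 5 (0.0587), control 7 (0.0799), 7-week 31 (0.0685) or 7-week 39 (0.0663). Pde1c and Cat lost it without any 1 of 5 libraries (up to 0.0647 and 0.069), Cdkn1a without any 1 of 6 (up to 0.0729), and S100a9, Slc4a1 and Msln without any 1 of 7 (up to 0.0804, 0.0847 and 0.0852). Zfp281 and Efna1 lost it without any 1 of 8 libraries (up to 0.0895 and 0.0728), and Mme without any 1 of 11 (up to 0.0951). Among the lists, calcium handling was lost without control 7 (camera adjusted p = 0.0929), control 10 (0.134) or 7-week 31 (0.284), and the cell cycle without control 1 (0.109), control 5 (0.0614) or 7-week 31 (0.407). The clock list was lost without control 4 (0.142), control 5 (0.132), 7-week 31 (0.0919), 7-week 39 (0.092) or 7-week 40 (0.0587), and immediate early genes without any 1 of 6 libraries (up to 0.175).

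**Figure D2:**
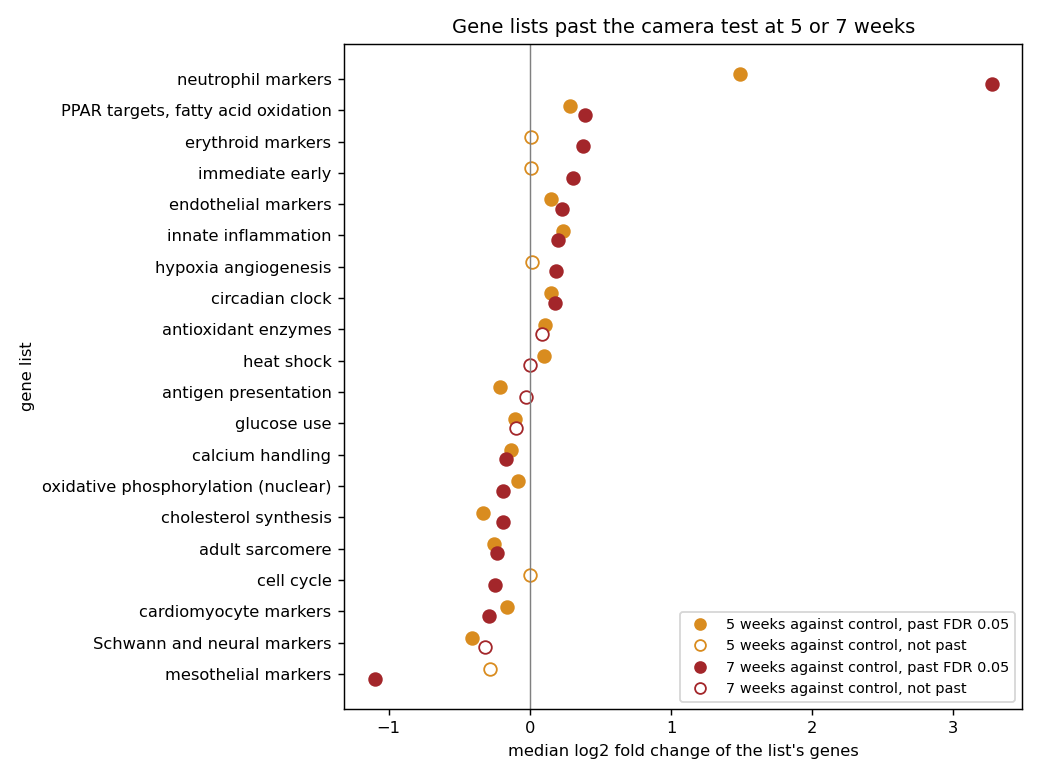
Median log2 fold change of the 20 gene lists called by camera at 5 or at 7 weeks against control, with filled points for lists past an adjusted p of 0.05 and open points for the others. The neutrophil list had the highest median at both times (1.49 and 3.27), and the fatty acid oxidation list lay at 0.29 and 0.39.

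**Figure D3:**
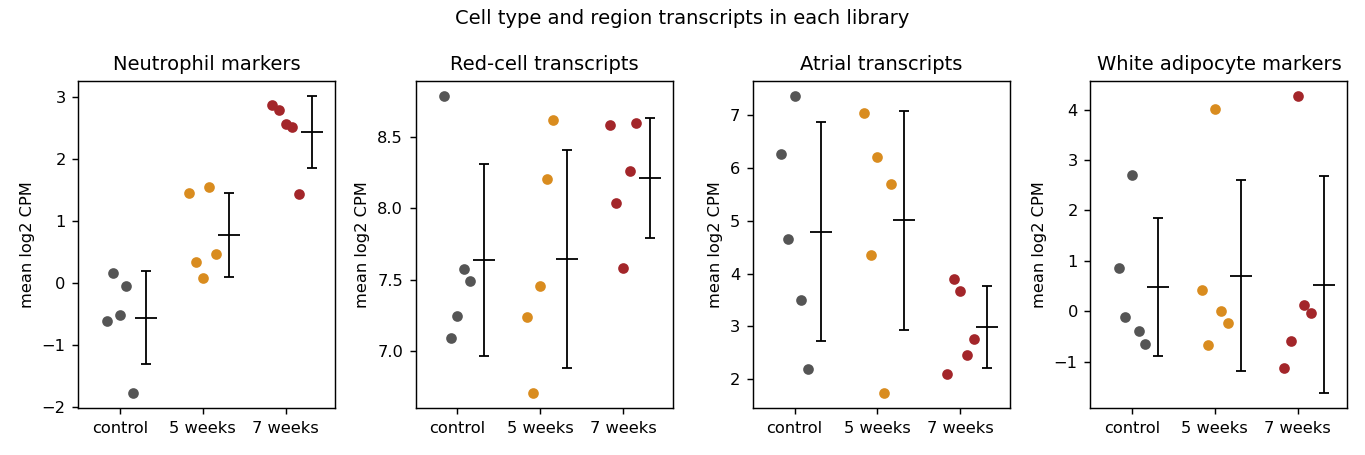
Mean log2 CPM of the transcripts of neutrophils, red cells, atrial muscle and white adipocytes in each library, with 1 point per library and a bar for the mean ± SD per group (n = 5). The neutrophil mean was 1.33 higher at 5 weeks and 2.99 higher at 7 weeks than in controls. The red-cell, atrial and white adipocyte means each cover part of their marker list.

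The third comparison asked whether hearts differed between 7 and 5 weeks of the model. No gene was called by edgeR, with 0 higher and 0 lower, a smallest adjusted p of 0.0997 and 1175 genes at an unadjusted p below 0.05. DESeq2 called 53 higher and 29 lower, and limma-voom called 0 and 0. The genes nearest to the threshold were Sorl1, a sorting receptor (log2 fold change 0.48, SE 0.07), and Col4a2, a basement membrane collagen (0.54, SE 0.08), both with an edgeR adjusted p of 0.0997. Nr4a1, Adamts10, Tmem41b and Rasal2 followed at 1.13 (SE 0.19), −0.41 (SE 0.07), 1.2 (SE 0.21) and 0.90 (SE 0.16), each with an edgeR adjusted p of 0.12. In 1.61% of tested genes the 2 groups did not overlap, against 0.794% by chance. Without 7-week 31 edgeR called 4 genes and without 5-week 21 it called 1. The panel of 24 genes gave log2 fold changes between −1.13 and 0.51 with no adjusted p below 0.391. Il1b stood at 1.13 (SE 0.26), Pln at −0.87 (SE 0.21), Myl4 at −2.44 (SE 0.87; −1.84 without 5-week 21) and Nppa at −1.13 (SE 0.59).

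Of 42 lists 12 were called between 7 and 5 weeks by camera, although none of their members was called over all genes. Higher at 7 weeks were the lists of neutrophil (median log2 fold change 1.55, camera adjusted p = 6.04e-10, 6 risen adjusted over the list alone), erythroid (0.55, 6.22e-05, 1 risen), immediate early (0.25, 0.00144, 4 risen), cholesterol (0.12, 0.00672, 4 risen), mural cell (0.18, 0.015, 2 risen) and hypoxia genes (0.06, 0.0291, 3 risen). Lower were those of oxidative phosphorylation (−0.12, 2.85e-12, 11 fallen adjusted over the list alone), atrial muscle (−1.32, 0.00225, 0 fallen), heat shock (−0.12, 0.00244, 1 fallen), cardiomyocytes (−0.10, 0.00645, 4 fallen), mesothelium (−0.74, 0.0319, 6 fallen) and cell cycle (−0.29, 0.0468, 0 fallen). Their adjusted p with an estimated correlation ran from 0.232 to 0.812 and fry passed for none, so no list call held there. Examples are the neutrophil gene Ngp (log2 fold change 3.55, SE 0.85), Slc4a1 (1.52, SE 0.38), the mural receptor Notch3 (0.35, SE 0.09), Ndrg1 (0.36, SE 0.07), the respiratory chain gene Cox6c (−0.23, SE 0.05), Dnaja1 (−0.57, SE 0.14; −0.37 without 5-week 28), the mesothelial gene Upk1b (−1.20, SE 0.33) and the replication gene Mcm5 (−0.53, SE 0.18). The other 30 lists had camera adjusted p between 0.079 and 0.978. In 11 lists, none of them called, the median, mean and test differed in sign (sarcomere, calcium handling, clock, mitochondrial DNA, antioxidant, autophagy, iron and haem, T and NK cell, white adipocyte, Schwann and lung). Without 7-week 31 the calls of heat shock (camera adjusted p = 0.0585) and cardiomyocytes (0.102) were lost, and without 7-week 34 those of cholesterol (0.0631) and mural cells (0.0906). The hypoxia and mesothelium calls were each lost without any 1 of 5 libraries (up to 0.113 and 0.207) and that of the cell cycle without any 1 of 7 (up to 0.773). With an atrial score as covariate the atrial list had a camera adjusted p of 0.822, which follows from building the score from members of that list.

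The contrasts against control share the same 5 control libraries, so their relation was set against simulation and against split controls. Of the called genes 51 were higher at both times and 48 lower at both, 99 in all, and 0 went opposite ways, against 0.795 and 0.682 for independent lists. In simulations where neither group differed from the shared controls the mean overlap was 0.01, but these called a mean of 0.07 genes at 5 weeks and 0.03 at 7 weeks, so they do not measure what shared controls add to an overlap. Fabp3, Cd36 and Chrna2 were among those higher at both times, and Tnnt2, Mybpc3, Eno3 and Spon2 among those lower. Of the 170 genes called at 5 weeks 169 (99.4%) had the same sign at 7 weeks, and of the 297 called at 7 weeks 296 (99.7%) had the same sign at 5 weeks. In simulations where only the controls were shared, as many genes of lowest p had the same sign in 91.9% (85.9% to 97.6%) and 91.0% (86.9% to 94.9%). Shares up to 97.6% and 94.9% can thus arise from shared controls alone. The observed 99.4% and 99.7% lay above every simulated set. In the fits with split controls, where the contrasts share no library, the medians were 89.4% and 89.1%. Shared libraries cannot account for the agreement in those fits. Its source, the model or another difference from controls common to both groups, was not tested. A further 71 genes were called at 5 weeks alone and 198 at 7 weeks alone, but the direct test between 7 and 5 weeks called 0 genes. Over genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.574, against a mean of 0.498 (0.412 to 0.565) from shared controls alone in simulation, and the covariance was 0.199 against 0.151. The simulated genes were drawn independently of each other. The simulated ranges of r and of the shares with the same sign may therefore be narrower than with correlated genes. With the controls split between the contrasts, over 20 fits, r was 0.129 (0.0871 to 0.155), the median covariance 0.0977 and the median overlap 7 genes (2 to 15) with medians of 43.5 calls in each contrast. The same sign was shared by 72.5% of genes, against 66.5% in simulation and a median of 60.5% with split controls. The overlap of 99 fell to 43 without control 4, to 60 without control 5 and to 52 without control 7, to 14 without control 5, 5-week 28 and 7-week 34, to 45 without 7-week 31 and 32, and to 54 with an atrial score as covariate.

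**Figure D4:**
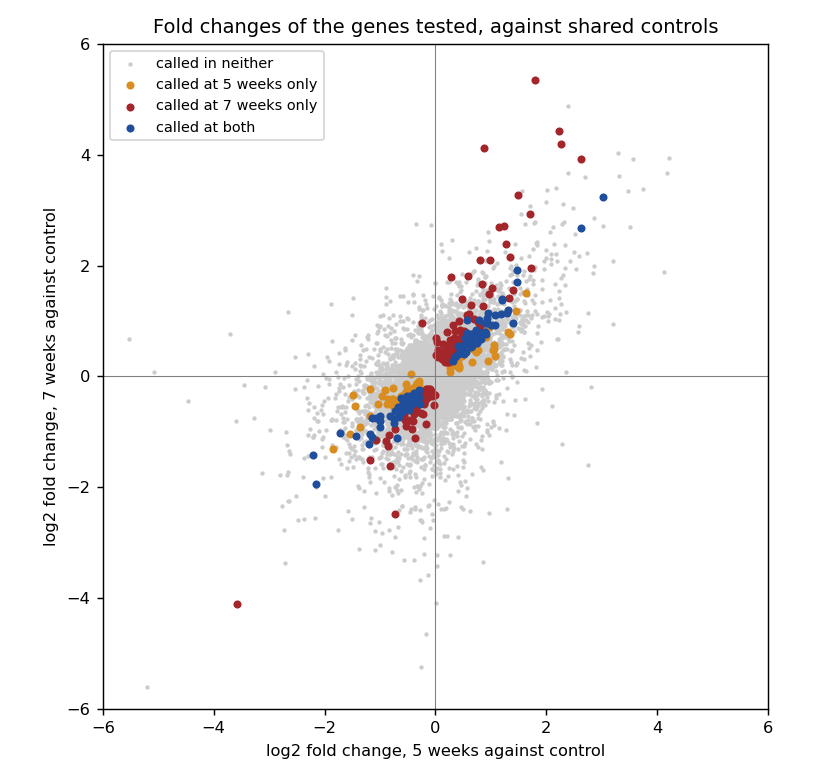
Log2 fold change of each tested gene at 5 weeks against control (x axis) and at 7 weeks against control (y axis), with the axes ending at 6 in each direction and 34 uncalled genes beyond them. The 99 genes called at both times lie in the quadrants where both changes have the same sign, and both axes use the same 5 controls.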

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

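The tests of red-cell, other cell type, atrial, clock and glucocorticoid transcripts in this part were chosen only after the results were seen, while the counts over other splits of the libraries were planned.

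Of 9 neutrophil markers tested 6 rose at 7 weeks (median log2 fold change 3.27, SE 0.46; adjusted p of the list 0.0768 with an estimated correlation; permutation p of the mean 0.0952 adjusted over 12 tests), and S100a8 at 16.2 ± 8.23 CPM (SD, n = 5) and S100a9 also stand in the list of innate inflammation. More whole blood left in the tissue would raise red-cell transcripts as much. The 5 abundant ones looked at had a median of 0.37 and a highest upper bound of 1.86 (fold change plus 2 SE), which argues against blood alone. They leave out Slc4a1, the called red-cell gene, at 1.80, and the wider erythroid list passed the camera test upward (adjusted p = 0.00212). Some added blood therefore stays possible. A lower share of cardiomyocyte transcripts would raise the markers of all other cells alike. Among 11 lists of other non-muscle cells the medians ran from −1.10 (mesothelium) to 0.79 (white adipocytes), below the neutrophil median, which argues against that as well. The highest upper bound was 1.12 (median plus 2 SE). The SE of a list, 0.46 for neutrophils included, measures the spread over its genes and not between libraries. Between libraries the white adipocyte score had an SD of 2.15 at 7 weeks and 1.37 in controls, so 1.12 does not bound the difference between groups. More neutrophils in the heart, more neutrophils in an unchanged amount of blood, or higher expression per cell may each account for the rise, and these data do not separate them. The treatment itself stays among the open explanations as an untested hypothesis.

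The 4 transcripts of the atrial score had a mean of −1.81 relative to controls at 7 weeks on the log2 scale (−1.17 without control 5), less than the span of 5.18 among the 5 controls (exact two-sided permutation p = 0.127). None of 9 markers in the wider atrial list was called (camera adjusted p = 0.0809). If the pieces held different shares of atrial tissue, Myl4, Myl7 and Sln should move together, and the lowest pairwise Pearson r of their deviations from group means over 15 libraries was 0.917 (Spearman's rho 0.961; permutation p = 1e-05 for both, the smallest they can give, and 1e-05 adjusted over 3 relations; r = 0.897 without the 2 libraries farthest from the median). With the atrial score as a covariate the log2 fold change of Nppa was −0.0503 (SE 0.42), against −1.46 (SE 0.59) without it. Without control 5 these were 0.0754 (SE 0.33) and −0.54 (SE 0.43), which lie within 2 SE of each other, so lower Nppa expression beyond the atrial share stays open. A smaller atrial share in the 7-week pieces may account for the pattern, and whether it came from dissection, from chance among 5 libraries or from the treatment stays open.

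Clock transcripts moved at 5 weeks, Arntl and Nr1d1 down and Per2 and Cry1 up. A later hour of collection in the light phase was taken to predict lower Npas2 and Clock and higher Per1 and Per3, beside the 4 genes that prompted the test. Of Npas2, Clock, Per1 and Per3, 3 had that sign by more than 2 SE. Clock stood at −0.20 (SE 0.20) and the clock target Dbp at −0.01 (SE 0.30). The signs expected of clock genes, Nr1d1 and Cry1 among them, depend on which hours are compared. The hours are not in the labels, so these values cannot decide on the hour. Glucocorticoid exposure predicts a rise of genes it switches on, and 12 such genes had a median log2 fold change of 0.60 (SD 0.56). The 12 include Fkbp5, which was already called at 5 weeks, so their rise is no independent support. Between 7 and 5 weeks none of the 12 had an edgeR adjusted p below 0.528. At 7 weeks their median was 0.96 (SD 0.56), while all 4 clock genes that did not prompt the test lay nearer to control than at 5 weeks, 0 of them by more than 2 SE, and so did Nr1d1, Cry1 and Per2 by more than 2 SE (log2 fold change 0.54, −0.41 and −0.43 between 7 and 5 weeks; lowest adjusted p 0.408), which counts against this source but which their choice at 5 weeks favours too. A difference in the hour, in stress hormones or an effect of the treatment on the clock could each contribute, and the values here exclude none of them.

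Of the 126 ways to divide the 10 libraries of a contrast, 100 splits were drawn. At 5 weeks 1 of them gave at least 170 genes, the labelled one (highest other 2). At 7 weeks 1 gave at least 297, again the labelled one (highest other 3). Chance is thus unlikely for both counts, at 1 of 100, the smallest share the test can give. Other splits mix the groups, which adds any difference between groups to their spread. The splits do not separate the treatment from other differences between the groups of libraries. For the called lists 3 of 100 splits, the labelled one included, gave at least 15 at 5 weeks (highest other 16) and 3 of 100 at 7 weeks (highest other 16). Chance is unlikely for the number of lists only at a share below 0.05, since other splits reached that number and their median was 7 lists. Between 7 and 5 weeks 16 of 100 splits gave at least the 12 lists found (highest other 15), so chance cannot be excluded for them. With 0 genes found there, 100 of 100 splits give at least as many whatever the data (highest other 2), so that count tests nothing.

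The lists past the direct camera test between 7 and 5 weeks were oxidative phosphorylation (adjusted p = 2.85e-12), neutrophil (6.04e-10), erythroid (6.22e-05), immediate early (0.00144), atrial (0.00225), heat shock (0.00244), cardiomyocyte (0.00645), cholesterol (0.00672), mural (0.015), hypoxia (0.0291), mesothelial (0.0319) and cell cycle (0.0468). With an estimated correlation their adjusted p ran from 0.232 to 0.812 and the fry test passed none, so these differences did not hold under either.

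In 22 of 156 sets of 5 libraries (14.1%), over 47 genes and 5 library measures, 1 library stood far from the other 4, where chance gives about 1 in 20, and 8 of the 22 concerned 7-week 31. In 7-week 31 Pdk4 stood at 2310 CPM (others 304 to 870), Serpina3n at 102 (30.1 to 43.3), Ucp3 at 86.8 (49.2 to 55.4) and Angptl4 at 67.9 (21.8 to 29). In the same library Cyp1a1 stood at 13.3 CPM (39 to 47.2), Fam107a at 10.8 (25.8 to 31.8) and Sqle at 0.838 (2.44 to 3.01), and mitochondrial DNA transcripts made up 0.479% of counts (0.00202% to 0.00612%). In 7-week 32 the total was 15138097 counts (36063309 to 39072276) and 18014 genes were above 0 (19818 to 20339). In 7-week 34 Krt7 stood at 0.348 CPM (1.13 to 1.30), and in 7-week 39 Rasal2 stood at 55.1 CPM (61.9 to 64.4). Among controls, Spon2 stood at 22.9 CPM (6.49 to 10.9) in control 4, Nppa at 1302 CPM (118 to 441) and Tmem41b at 16.0 CPM (26.7 to 29.7) in control 5, and Cyp1a1 at 21.7 CPM (9.22 to 12.2) and haemoglobin transcripts at 0.304% of counts (0.0899% to 0.137%) in control 1. At 5 weeks, Lingo3 stood at 4.23 CPM (8.02 to 9.24) and Chil3 at 2.75 CPM (0.864 to 1.36) in 5-week 29, Col4a2 at 379 CPM (312 to 325) in 5-week 30, Adamts10 at 69.6 CPM (61.2 to 62.6) in 5-week 28 and Col3a1 at 158 CPM (219 to 234) in 5-week 23.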

How the results depend on the processing

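Near-zero values set to missing, genes with 3 or more exons, the 2 sets of libraries left out together and the atrial covariate were tests chosen only after the results were seen, as were all settings of the overlap except the FDR of 0.10, split controls, DESeq2 and limma-voom. Among 71 called results of named genes 0 reversed, 17 kept their call in every other setting run for named genes and 43 kept it without each single library. Of 42 list calls 19 kept theirs in every counted refit of camera with the preset correlation, and 23 without each single library. The refit with upper-quartile factors was not counted. Most list calls were lost with an estimated correlation and in fry, as given below.

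Genes higher and lower at 5 weeks, 78 and 92 as reported, were 121 and 144 with a filter of 5 CPM in 5 libraries (11144 genes tested), 321 and 324 by DESeq2, 124 and 148 by limma-voom with quality weights, 27 and 31 with 4 surrogate variables, and 16 and 19 without control 5, 5-week 28 and 7-week 34. At least 2-fold there were 20 and 18, and 45 fell at least 1.5-fold, which follows from the added threshold. At 7 weeks, 172 and 125 as reported, they were 465 and 387 by DESeq2, 66 and 27 with surrogate variables, 16 and 15 without control 5, 5-week 28 and 7-week 34, 55 and 24 without 7-week 31 and 32, and 58 and 65 with the atrial covariate. With fold thresholds there were 102 and 49 (1.5-fold) and 41 and 17 (2-fold), and the lower count was 200 with upper-quartile factors, 68 without a filter (30920 genes tested) and 73 with only the 2 groups compared. Between 7 and 5 weeks, 0 and 0 as reported, there were 53 and 29 by DESeq2, 6 and 1 with near-zero values missing, 1 and 1 without control 5, 5-week 28 and 7-week 34, and 1 higher without 7-week 31 and 32. The overlap of 99 was 333 by DESeq2, 214 at an FDR of 0.10, 65 without a filter, 28 with surrogate variables, 14 without control 5, 5-week 28 and 7-week 34, 45 without 7-week 31 and 32, 54 with the atrial covariate and a median of 7 with split controls, where fewer controls serve each contrast. Of the called lists 1, 0 and 0 passed with an estimated correlation and 3, 8 and 0 in fry for 5 weeks, 7 weeks and 7 against 5 weeks. Leaving out 1 library at a time gave 34 to 123 higher and 48 to 132 lower at 5 weeks, 71 to 166 and 40 to 125 at 7 weeks, 0 to 4 higher between 7 and 5 weeks and 43 to 98 in the overlap. Under other scalings the median log2 fold change of all genes lay between −0.04 and 0.01. Apart from added thresholds and fewer libraries, the cause was not tested.

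Log2 fold changes that turned sign were all of uncalled results, and the cause was not tested. With limma-voom Nppa was 0.063 and Dbp 0.11 at 5 weeks, and Dbp was 0.095, Postn −0.025 and Nos2 −0.0088 at 7 weeks. With surrogate variables Dbp was 0.18 at 5 weeks and 0.14 at 7 weeks, Nos3 0.014 and Hspa5 −0.0028. With upper-quartile factors Nos2 was −0.027 at 7 weeks. Without control 5, 5-week 28 and 7-week 34, Nppa was 0.54 and Dbp 0.067 at 5 weeks, and Dbp was 0.0902, Nppb −0.074 and Nos3 0.035 at 7 weeks. Without 7-week 31 and 32, Dbp was 0.12, Acta1 −0.019 and Xbp1 −0.035. With the atrial covariate Nos3 was 0.032 at 7 weeks and Nppa 0.027 between 7 and 5 weeks. Over single libraries left out, at 5 weeks Nppa ran from −0.57 to 0.59, Dbp from −0.24 to 0.12, Ankrd1 from −0.10 to 0.11 and Xbp1 from −0.073 to 0.012. At 7 weeks Nppb ran from −0.026 to 0.23, Acta1 from −0.013 to 0.13, Ankrd1 from −0.015 to 0.18, Postn from −0.14 to 0.22, Xbp1 from −0.024 to 0.16, Hspa5 from −0.055 to 0.13, Nos3 from −0.11 to 0.00048, Nos2 from −0.099 to 0.072 and Dbp from −0.27 to 0.089. No pseudocount or quantile alternative was run, because those apply to normalized values, and no paired analysis was possible because the groups share no replicate numbers. At this depth and spread a simulated change of 0.5 on the log2 scale was recovered for 7.58% of changed genes at 5 weeks and 15.2% at 7 weeks, so small changes were mostly not detectable.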

Other observations

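The counts by exon number in this part were chosen as tests only after the results were seen, and the medians of T and NK cell and of macrophage markers were also looked at after the results were seen. The gene lists were tested by camera as planned, and the shares of counts are library measures without a test.

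Lists not called as a whole at either time, though some of their genes were (Fabp4 among white adipocyte markers, Cidea among brown), included the markers of macrophages, B cells, T and NK cells, fibroblasts, brown and white adipocytes, skeletal muscle, lung, thymus and liver, and the extracellular matrix, interferon and unfolded protein lists. T and NK cell markers had a median at 7 weeks of −0.40 on the log2 scale (2 SE 0.17), and macrophage markers one of −0.09 (2 SE 0.21). These SE measure the spread over the genes of a list, not between libraries.

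Gm28661, a gene model whose sequence resembles mitochondrial DNA, took 1.42% ± 0.124 of the counts in controls, 1.63% ± 0.0938 at 5 weeks and 1.63% ± 0.144 at 7 weeks (SD, n = 5 each), while transcripts of mitochondrial DNA itself took 0.00236% ± 0.00314 in controls. How reads were shared out between them was not tested, so neither share was read as an amount in the tissue. Genes with 1 or 2 exons were 5 of the 170 genes called at 5 weeks (2.94%) and 15 of the 297 called at 7 weeks (5.05%), against 13.1% of tested genes.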
